A study of Arabidopsis thaliana with 11 samples.

How the data were processed

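Arabidopsis RNA was measured on 11 Affymetrix ATH1 arrays, 3 of rosette leaf, 4 of flower and 4 of stem. The deposited values are intensity values, 1 MAS5 signal per probe set on a linear scale, per the submitters' processing notes. The version of MAS5, the scaling target and detection calls are not given in the sources used here. On every array the mean without the lowest and highest 2% of values was 99.96 to 99.97, which was checked on the values. The number of arrays limits the precision of every value.

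Of 22810 probe sets, 64 are controls, 13513 name 1 gene in the annotation used here, 503 name several and 8730 name none. Results for unnamed probe sets enter counts only. The genes CESA1, CESA3, CESA6, CESA4, CESA7, CESA8, AP1, AP3, PI, AG and SEP3, which were to be named whatever their values, are not named in the annotation used here and were not analysed here.

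Signals were taken to log2 as deposited. The dim limit was the 40th percentile of all values, a signal of 28.1, and a probe set was kept where at least 3 of the 11 arrays lay above it, without regard to group, which left 15718, of which 8583 name 1 gene. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over the probe sets kept and a call at an adjusted p under 0.05. Tissue comparisons used all 11 arrays with the title code as a covariate. The comparison of GH with GC over the tissues had tissue as a covariate, and the comparisons within tissues and the difference of the GH effect between flower and stem used 1 mean per tissue and code. Where every array of a tissue lay under the dim limit, the fold is given as a lower bound against the higher of the limit and the array's own value. Errors of signals are SD over arrays and errors of log2 fold changes are SE of the model.

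Genes were named by a rule set before the data were examined. For each tissue comparison and direction it took, among called probe sets of 1 gene whose tissues do not overlap, the 4 largest log2 fold changes with both means above the limit and the 4 highest means where the other tissue was dim on every array. Ranks such as the largest rise or fall are among these probe sets of 1 gene. For GH against GC it took up to 3 per direction, and from each gene list up to 4 members with the lowest adjusted p. There were 25 gene lists fixed before the data were examined, with 472 genes, of which 59 are on named probe sets and 49 were kept. Of these lists 10 had the minimum of 3 measured members. A further 34 lists were drawn up after the annotation was read and before any value was tested, and 32 of them were tested. Lists were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison and set, and again with an estimated correlation and with fry, whose p tests whether a list's genes move one way on balance.

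The alternatives were quantile normalization, centring on the 75th percentile, no filter, a filter at the 60th percentile, a pseudocount at the 20th percentile (8.86), values floored at the dim limit, eBayes without the trend, each array left out, no covariate, a replicate block, fits within a code and fits on the compared arrays alone. A covariate for the 3' over 5' ratios of control genes, and leaving out stem GH 1 and leaf GC 1 together, were added after the data were seen. Calls were also counted in other splits of the arrays. The method was tested on simulated data with the noise level of these arrays, drawn independently for each probe set and array. In these data 100 probe sets per comparison were changed 2-fold and 100 were changed 4-fold. The real tissue comparisons called 35.7% to 40.9% of probe sets, and noise shared across genes was not simulated. The following shares therefore hold for the simulated setting, with 1 simulated data set per comparison. Differences between these shares include the variation of a single draw. Of the 2-fold changes, 29% to 47% were found in the tissue comparisons, 59% for GH over the tissues, 12% in flower, 7% in stem, 1% in leaf and 0% for the difference of the GH effect. Of the 4-fold changes, 76% to 90% were found in the tissue comparisons, 83% for GH over the tissues, 69% in flower, 58% in stem, 40% in leaf and 36% for the difference. The share of false calls was 2.14% to 3.67% in the tissue comparisons and 5.96% to 11.0% in the GH comparisons, the highest in stem. Control probe sets were used only to judge RNA quality.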

Results

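RNA from 11 samples of Arabidopsis thaliana Columbia-0 (Col-0), a standard laboratory accession, was hybridised to ATH1 arrays, which carry 22810 probe sets each. Rosette leaves were taken 15 days after germination (3 arrays). Flowers with buds (4 arrays) and the upper part of the stem, freed of siliques and pedicels (4 arrays), were taken at 29 days. Plants had a photoperiod of 16 h at 125 umol of light per square metre and second, with 25 C by day and 20 C by night. Each array's title carried the code GC or GH: 1 GC and 2 GH arrays in leaf, and 2 of each in flower and in stem. The descriptions gave a greenhouse for the GH arrays of leaf and a controlled system for every other array, including the GH arrays of flower and stem, so the labels did not settle what the code stood for. Leaf differed from flower and stem in plant age as well as in tissue. The labels did not say whether replicates came from separate plants, so the p-values measured the spread between these samples, which may be technical.

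The deposited signals had a trimmed mean of 99.96 to 99.97 on every array. The share of probe sets above the dim limit, a signal of 28.1, was 57.6% to 58.4% in leaf, 57.5% to 58.8% in stem and 62.5% to 64.6% in flower. Pearson's r between log2 signals across probe sets was 0.918 to 0.953 within leaf, 0.912 to 0.938 within flower and 0.878 to 0.923 within stem. Between tissues it was 0.662 to 0.779. The first principal component, with 42.2% of the variance, set flower apart, and the second, with 30.7%, set leaf apart from stem.

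**Figure D1:**
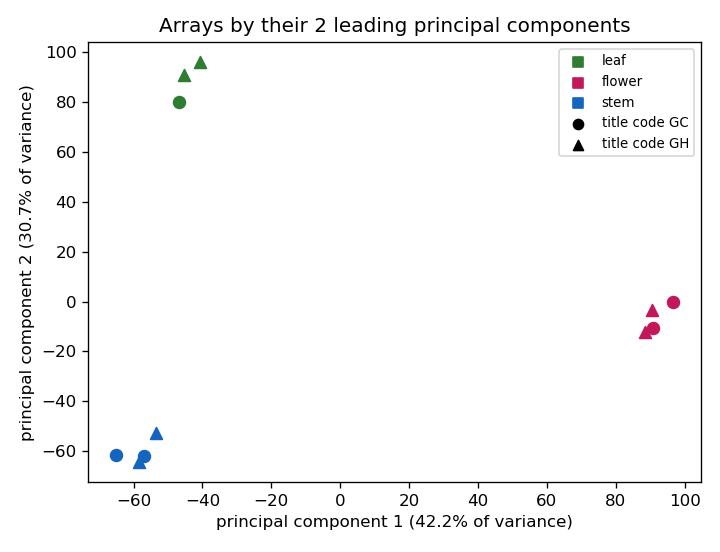
Each point is 1 of the 11 arrays on the first principal component (horizontal axis, 42.2% of the variance) and the second (vertical axis, 30.7%), with colour for tissue and shape for title code. Arrays of 1 tissue lie together whatever their code.

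RNA quality differed between arrays and between tissues. The 3' over 5' signal ratio of actin was 19.6 on stem GH 1 and 0.781 to 2.90 on the other arrays. The ratio of ubiquitin was 2.42 and that of GAPDH 1.77 on stem GH 1, each the highest of the 11 arrays. The mean log2 ratio over these control genes was 0.53 on both flower GC arrays, 0.90 and 0.80 on the flower GH arrays, -0.24 to 0.09 on the leaf arrays and 0.01 to 0.24 on the other stem arrays. The 5S ribosomal RNA signal was 1.73 to 6.47 in leaf, 78.1 to 139 in flower and 49.4 to 196 in stem.

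**Figure D2:**
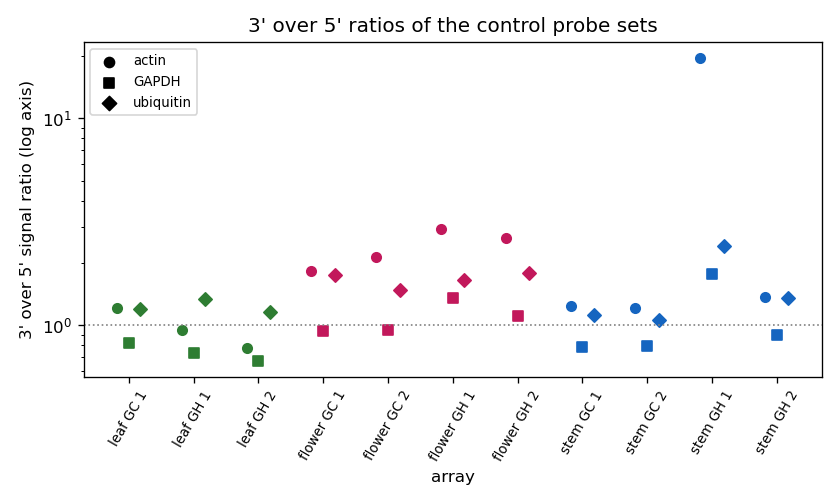
The 3' over 5' signal ratios of actin, GAPDH and ubiquitin (vertical log axis, no unit) are plotted per array (horizontal axis), with colour for tissue. The actin ratio of stem GH 1 is 19.6, against 0.781 to 2.90 on the other arrays.

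The first comparison asked which transcripts differed between flowers and rosette leaves. Genes of the anther and of pollen stood out in flower. ATA27, which encodes a beta-glucosidase of the tapetum, had a signal of 1013 ± 77.5 (SD, n = 4) in flower and lay under the dim limit on every leaf array, a difference of at least 36.0-fold. PLIM2a, a pollen actin-bundling protein, was at least 11.3-fold higher in flower. Photosynthesis genes were lower there: LHCB4.2, a light-harvesting protein of photosystem II, had 582 ± 134 (SD, n = 4) in flower against 2511 ± 868 (SD, n = 3) in leaf. The signal of AT2G20870 was 4515 ± 467 (SD, n = 4) in flower against 112 ± 93.3 (SD, n = 3) in leaf, the largest log2 rise measured above the limit in both tissues (5.67 ± 0.39 SE, adjusted p = 1.2e-06).

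Other large rises in flower were those of AT3G28500, an acidic ribosomal protein P2 (4.86 ± 0.26), AT4G33150, the lysine-degrading enzyme LKR/SDH (3.66 ± 0.23), and AT1G48750, of the lipid transfer protein family (3.61 ± 0.27), as log2 fold changes with SE. Among genes dim on every leaf array, AT1G66850, another lipid transfer family member, was at least 125-fold higher in flower, AT1G68875 at least 57.0-fold, AT2G47050, a pectin methylesterase inhibitor family member, at least 41.8-fold, and AT3G07820, a polygalacturonase, at least 38.3-fold. The largest falls were those of AT4G34950, of the major facilitator family (-4.80 ± 0.35), AT2G41090, a calmodulin-like protein (-4.51 ± 0.20), AT2G25510 (-4.49 ± 0.26) and AT5G03350, of the legume lectin family (-4.30 ± 0.36). Among genes dim on every flower array, the thionin AT1G66100 was at least 33.1-fold lower, the defensin PDF1.2b at least 17.3-fold, and the defensin-like AT3G05730 at least 11.1-fold. AT5G59540 was at least 13.2-fold lower. The adjusted p of these 16 genes was 5.9e-08 to 1.4e-05.

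All 6 measured genes of light harvesting and the photosystems, all 3 of the Calvin-Benson cycle and all 3 of photorespiration fell in flower (camera adjusted p = 1.7e-07, 5.8e-04 and 5.8e-04). Adjusted over the list alone, the counts were the same. Examples were LHCB4.2 (-2.19 ± 0.14), the Rubisco activase RCA (-1.998 ± 0.21) and the hydroxypyruvate reductase HPR (-2.03 ± 0.18). These calls were lost with adjusted p = 0.0927, 0.0972 and 0.0927 with an estimated correlation. The 3 measured glucosinolate genes also fell, 3 of them adjusted over the list alone (adjusted p = 0.00277, and adjusted p = 0.0972 with an estimated correlation). BCAT4, an aminotransferase of methionine chain elongation, fell by 3.998 on the log2 scale. The 4 measured genes of mature pollen rose, 4 of them adjusted over the list alone (adjusted p = 0.0165, and adjusted p = 0.0972 with an estimated correlation). They included AtVEX1, named for expression in the vegetative cell of pollen, at least 3.87-fold higher, and the actin ACT11 (1.07 ± 0.20), which is not restricted to pollen and lost its call within the GC arrays (adjusted p = 0.118). Of 4 cold and drought genes, 3 rose, or 4 adjusted over the list alone (adjusted p = 0.00306, and adjusted p = 0.126 with an estimated correlation), among them the dehydrin COR47 (2.08 ± 0.15).

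A sign of RNA quality moved with the tissues: the mean log2 3' over 5' ratio was 0.53 to 0.90 on the flower arrays and -0.24 to 0.09 on the leaf arrays. The 5S ribosomal RNA signal was 78.1 to 139 in flower and 1.73 to 6.47 in leaf, and its relation to RNA quality was not tested. The following lists were chosen after the probe annotation was read and before any value was tested. Among 29 nuclear genes of chloroplast photosynthesis and chlorophyll synthesis, 26 fell and none rose (adjusted p = 1.3e-19, and 0.0268 with an estimated correlation). Of 20 anther and pollen genes, 15 rose and none fell (adjusted p = 9.6e-05, and 0.0268 with an estimated correlation). These were the only list calls in the 8 comparisons that held with an estimated correlation. In the carboxypeptidase-like scpl family, 14 of 20 genes rose and 2 fell (adjusted p = 0.00711, and adjusted p = 0.0803 with an estimated correlation), with scpl48 at 2.48 ± 0.16. Of 8 RALF-like signalling peptide genes 5 rose (adjusted p = 0.0267, and adjusted p = 0.294 with an estimated correlation), with RALFL32 at 1.80 ± 0.20. That list lost its call within the GC arrays (adjusted p = 0.101) and on the arrays of both tissues alone (0.0576). Of 14 flower and ovule development genes, 8 rose and 1 fell (adjusted p = 0.0428, and adjusted p = 0.188 with an estimated correlation). The last call was kept in 15 of 25 alternatives and lost without flower GH 2 (adjusted p = 0.0771), flower GC 2 (0.0536), stem GC 1 (0.0533) or stem GC 2 (0.0526). It was also lost with no filter (adjusted p = 0.154), with the filter at the 60th percentile (0.0615), with a replicate block (0.0579), within the GC arrays (0.0905), within the GH arrays (0.0761) and on the arrays of both tissues alone (0.0576). The carpel and fruit regulators ALC (2.05 ± 0.29) and SPT (1.45 ± 0.21) were among its genes.

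In limma's test, 5617 of 15718 probe sets differed between flower and leaf at an adjusted p under 0.05, 3354 higher and 2263 lower in flower. At least 2-fold changes made up 2068 of the rises and 1409 of the falls. The median log2 difference of all probe sets tested was 0.16 as deposited, -0.00 after quantile normalization and 0.03 after centring each array on its 75th percentile. The split then became 2781 higher and 2677 lower with quantile normalization, and 2650 higher and 2699 lower with centring. Within the GC arrays alone, with 1 leaf array, 2612 probe sets differed.

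The comparison of stem with leaf asked the same of the other organ taken at 29 days. IRX15, needed for normal xylan in secondary walls, had a signal of 269 ± 98.5 (SD, n = 4) in stem and was dim on every leaf array, a difference of at least 8.93-fold. GUT2, a xylan backbone synthesis gene, had 422 ± 226 (SD, n = 4) in stem against 63.4 ± 2.77 (SD, n = 3) in leaf. The dehydrin LTI30 had 975 ± 194 (SD, n = 4) against 30.6 ± 13.2 (SD, n = 3). The legume lectin family gene AT5G03350 was lower, at 35.4 ± 22.6 (SD, n = 4) in stem against 717 ± 209 (SD, n = 3) in leaf.

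The largest measured rises in stem were those of AT1G72230, of the cupredoxin family (5.33 ± 0.32 on the log2 scale), LTI30 (4.95 ± 0.29), AT4G21650, a subtilase (4.71 ± 0.19), and the expansin-like EXLA1 (4.65 ± 0.39). Among genes dim on every leaf array, the cupredoxin AT1G22480 was at least 52.8-fold higher in stem, the aspartyl protease AT2G03200 at least 34.6-fold, EXLA2 at least 30.0-fold and AT2G37750 at least 18.9-fold. The largest falls were those of AT5G03350 (-4.73 ± 0.36), AT5G55620 (-4.65 ± 0.25), AT3G22240 (-4.08 ± 0.32) and AT3G44450, a cryptochrome inhibitor (-3.89 ± 0.41). Among genes dim on every stem array, AT1G23130 of the Bet v 1 family was at least 43.7-fold lower, the thionin AT1G66100 at least 33.1-fold, AT2G33850 at least 18.1-fold and PDF1.2b at least 17.3-fold. The adjusted p of these 16 genes was 1.3e-08 to 2.6e-05.

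All 3 measured secondary wall genes rose in stem, and 3 did adjusted over the list alone (adjusted p = 0.00260, and adjusted p = 0.171 with an estimated correlation): IRX15, GUT2 (2.46 ± 0.28) and IRX15-L. The IRX15-L signal was 355 to 664 in stem and 2.33 to 29.2 in leaf, where 1 of 3 arrays lay above the dim limit. Of 2 measured primary wall genes, CSLC04, a xyloglucan backbone synthase, rose (1.68 ± 0.27), while COB, which orients cellulose deposition, had a log2 fold change of 0.07 ± 0.19 and did not pass the test. Of 4 cold and drought genes, 3 rose, the same count adjusted over the list alone (adjusted p = 9.5e-04, and adjusted p = 0.190 with an estimated correlation), with COR47 at 3.49 ± 0.15. Of 6 light harvesting and photosystem genes, 5 fell, or 6 adjusted over the list alone (adjusted p = 0.0114, and adjusted p = 0.341 with an estimated correlation), with LHCB4.2 at -0.77 ± 0.14. Without the GH and GC code in the model LHCB4.2 lost its call (adjusted p = 0.0519). The list's call was lost with quantile normalization (adjusted p = 0.0621) and within the GH arrays (adjusted p = 0.0632), in a range of 9.8e-04 to 0.0632 over its alternatives. All 3 measured glucosinolate genes fell singly, also adjusted over the list alone, with BCAT4 at -1.80 ± 0.29, and the list as a whole did not pass (adjusted p = 0.0579). It passed without stem GH 1 (adjusted p = 0.0286), flower GH 2 (0.0338), stem GC 1 (0.0364), flower GH 1 (0.0463) or leaf GH 1 (0.0476), with no filter (0.0193), with a replicate block (0.0429), on the arrays of both tissues alone (0.0339), within the GC arrays (0.0437), with the 3' over 5' covariate (0.0240) and without stem GH 1 and leaf GC 1 (0.0313).

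Among lists chosen after the annotation was read, wall families rose in stem: 5 of 7 xyloglucan endotransglucosylase genes, 7 of 15 TBL wall acetyltransferase genes with 1 lower, and 5 of 9 GH9 endoglucanase genes (adjusted p = 0.00403, 0.00469 and 0.0269). They had adjusted p = 0.133, 0.133 and 0.149 with an estimated correlation. Examples were XTH16 (3.18 ± 0.44), TBL38 (3.12 ± 0.16) and GH9B5 (3.75 ± 0.16). Of the tetraspanin membrane proteins 5 of 8 rose (adjusted p = 0.00886, and adjusted p = 0.149 with an estimated correlation), TET3 by 1.58 ± 0.21 on the log2 scale. Of 9 ATG8 autophagy genes 4 rose, ATG8H by 1.95 ± 0.22 (adjusted p = 0.0470, and adjusted p = 0.519 with an estimated correlation). Among UGT glycosyltransferases 9 of 17 fell, UGT74D1 at least 2.59-fold (adjusted p = 0.0262, and adjusted p = 0.149 with an estimated correlation). Within the GC arrays UGT74D1 lost its call (adjusted p = 0.0968). Of 9 genes listed under organelle RNA editing 4 fell (adjusted p = 0.0269, and adjusted p = 0.149 with an estimated correlation). CRR41 (-1.97 ± 0.21) was among them, though a role of CRR41 in RNA editing was not established here. Without leaf GC 1 the GH9, UGT and RNA editing calls were lost (adjusted p = 0.101, 0.0604 and 0.0919). They were also lost without stem GH 1 and leaf GC 1 together (adjusted p = 0.124, 0.0578 and 0.107), the GH9 and RNA editing calls within the GH arrays (0.101 and 0.0690), the UGT and RNA editing calls with no filter (0.0636 and 0.0740), and the UGT call with the filter at the 60th percentile (0.206). The ATG8 call was kept in 12 of 25 alternatives and lost without leaf GH 1 (adjusted p = 0.104), leaf GH 2 (0.0579), stem GC 2 (0.0599) or stem GH 1 (0.197). It was also lost with quantile normalization (adjusted p = 0.0559), with the filter at the 60th percentile (0.0809), with a pseudocount (0.0509), with eBayes without the trend (0.0536), with a replicate block (0.0566), within the GC arrays (0.367), on the arrays of both tissues alone (0.0573), with the 3' over 5' covariate (0.295) and without stem GH 1 and leaf GC 1 (0.124).

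Among 29 nuclear genes of chloroplast photosynthesis and chlorophyll synthesis 23 fell, including HEME2, a uroporphyrinogen decarboxylase (-1.68 ± 0.15). Of 33 photosynthesis genes encoded in the plastid, 16 rose and none fell, including rbcL, the large Rubisco subunit (2.33 ± 0.25), and psbA, the D1 protein of photosystem II (2.52 ± 0.44). The adjusted p of these lists was 2.0e-07 and 1.1e-04, against adjusted p = 0.133 and 0.434 with an estimated correlation. Of 12 genes encoded in the mitochondrion 6 rose, nad4 by 1.26 ± 0.30 (adjusted p = 0.00948, and adjusted p = 0.310 with an estimated correlation). That list lost its call with the filter at the 60th percentile (adjusted p = 0.0786), within the GH arrays (0.0539, nad4 0.147) and without stem GH 1 and leaf GC 1 (0.0828, nad4 0.0835). Of 10 plastid ndh genes 5 rose and none fell, and of 19 plastid ribosomal and polymerase genes 7 rose and 1 fell, and neither list passed (adjusted p = 0.1297 and 0.0796). Both passed within the GC arrays, with 1 leaf array (adjusted p = 2.1e-04 for both), with the 3' over 5' covariate (0.0393 and 0.00982) and without leaf GH 2 (0.0123 and 0.0122). The ribosomal list also did with the floor at the dim limit (adjusted p = 0.0476), on the arrays of both tissues alone (0.0374) and without stem GH 1 (0.0269), flower GC 1 (0.0496) or flower GH 1 (0.0480). The 5S ribosomal RNA signal moved with these groups, at 1.73 to 6.47 in leaf and 49.4 to 196 in stem. Its relation to RNA quality was not tested. The mean log2 3' over 5' ratio was -0.24 to 0.09 in leaf and 0.01 to 0.24 in stem, with 2.13 on stem GH 1 apart. Whether the signals of organelle genes follow the amount of their transcripts was not tested. The mean log2 signal of the plastid photosynthesis genes was 8.32 on leaf GC 1, 8.65 on leaf GH 1 and 9.56 on leaf GH 2, against 9.50 on stem GH 1, the array with the actin ratio of 19.6, and 10.19 to 10.31 on the other stem arrays.

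Between stem and leaf, limma called 6222 probe sets, 2821 higher and 3401 lower in stem, of which 1795 and 1852 changed at least 2-fold. Within the GC arrays alone, with 1 leaf array, 3027 differed.

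Flower and stem were taken at the same age, so this comparison held age fixed. SWEET9, a sucrose transporter of nectaries, had a signal of 275 ± 32.6 (SD, n = 4) in flower against 27.2 ± 7.01 (SD, n = 4) in stem. AT2G20870 had 4515 ± 467 (SD, n = 4) against 32.6 ± 8.84 (SD, n = 4). Lower in flower was the cupredoxin AT1G22480, which had 1499.8 ± 253 (SD, n = 4) in stem and was dim on every flower array, a difference of at least 52.8-fold. HCT, an acyltransferase of lignin precursor synthesis, had 219.8 ± 46.6 (SD, n = 4) in flower against 928 ± 156 (SD, n = 4) in stem.

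**Figure D3:**
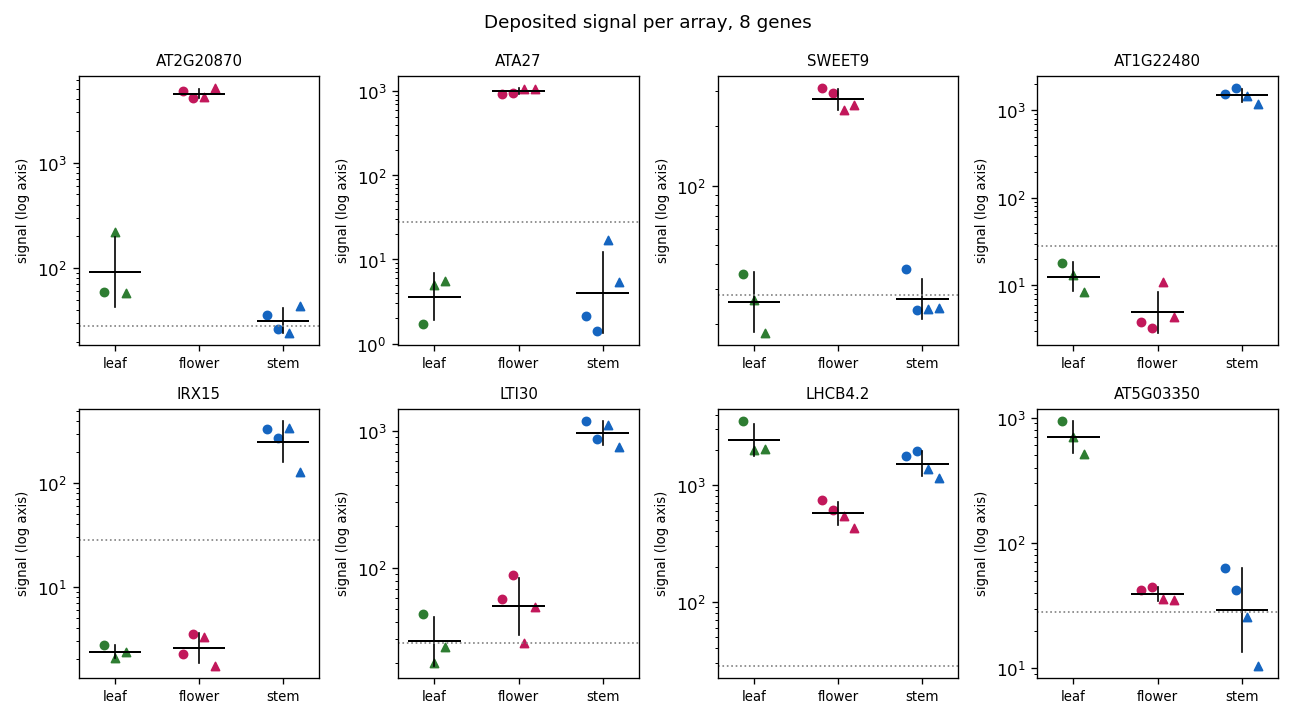
Deposited signals of AT2G20870, ATA27, SWEET9, AT1G22480, IRX15, LTI30, LHCB4.2 and AT5G03350 (vertical log axis) are shown per array in leaf, flower and stem (horizontal axis), with circles for GC and triangles for GH. Horizontal bars are means and vertical bars 1 SD of the log2 signals, and the dotted line is the dim limit of 28.1.

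The largest measured rises in flower over stem were those of AT2G20870 (7.15 ± 0.36 on the log2 scale), AT5G50030, of the pectin methylesterase inhibitor family (4.74 ± 0.25), the thiol reductase GILT (4.105 ± 0.63) and AT2G28790, a thaumatin-like protein (3.51 ± 0.17). Among genes dim on every stem array, AT1G68875 was at least 57.0-fold higher, AT4G23680 of the Bet v 1 family at least 47.6-fold, AT2G47050 at least 41.8-fold and AT3G07820 at least 38.3-fold. The pectin methylesterases PME61 (-4.41 ± 0.31) and PMEPCRF (-4.40 ± 0.20), the lipid transfer family gene AT5G05960 (-4.38 ± 0.26) and LTI30 (-4.20 ± 0.26) showed the largest falls. Among genes dim on every flower array, besides AT1G22480, AT3G23090 of the TPX2 family was at least 15.6-fold lower, IRX15 at least 8.93-fold and the xylanase family gene AT4G08160 at least 6.93-fold. The adjusted p of these 16 genes was 2.4e-08 to 3.6e-04.

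Every measured gene of 5 fixed lists moved one way in flower against stem, with the same counts adjusted over the list alone. The 6 light harvesting and photosystem genes, 3 Calvin-Benson genes and 3 photorespiration genes fell (adjusted p = 1.5e-05, 0.00426 and 0.00426), with LHCB4.2 at -1.42 ± 0.13, RCA at -1.22 ± 0.20 and HPR at -1.28 ± 0.17. The 3 secondary wall genes fell (adjusted p = 9.8e-04), with GUT2 at -2.66 ± 0.26 and IRX15-L at -4.001 ± 0.68, and the 3 cell cycle genes rose (adjusted p = 0.0280), with the Aurora kinase AUR1 at 1.35 ± 0.15. In the same order these lists had adjusted p = 0.105, 0.144, 0.105, 0.105 and 0.105 with an estimated correlation. Within the GC arrays the cell cycle call was lost (adjusted p = 0.0614). COB (-1.46 ± 0.18) and HCT (-2.08 ± 0.15) fell too. The mature pollen list did not pass (adjusted p = 0.291): 3 of its genes rose while ACT11 fell (-1.20 ± 0.18).

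Among lists chosen after the annotation was read, 9 of 14 SWEET sugar transporters were higher in flower and 2 lower (adjusted p = 0.0115, and adjusted p = 0.111 with an estimated correlation), with SWEET9 at 3.36 ± 0.21 and SWEET1 at 2.35 ± 0.26. Flower and ovule development genes rose in 9 of 14 cases, ALC by 2.401 ± 0.27 and SPT by 1.28 ± 0.19 (adjusted p = 0.00625, and adjusted p = 0.111 with an estimated correlation). Anther and pollen genes rose in 12 of 20 cases and fell in 3 (adjusted p = 0.0394, and adjusted p = 0.193 with an estimated correlation). ATA27 was at least 36.0-fold and PLIM2a at least 11.3-fold higher, and the tubulin TUB9 was lower (-0.86 ± 0.11). DNA replication and mitosis genes rose in 13 of 21 cases and fell in 1, with the topoisomerase TOPII at 1.88 ± 0.22 (adjusted p = 0.0394, and adjusted p = 0.292 with an estimated correlation). The replication call was kept in 18 of 25 alternatives and lost with quantile normalization (adjusted p = 0.0618) and without stem GH 1 (0.0739) or stem GC 1 (0.05003). It was also lost with the filter at the 60th percentile (adjusted p = 0.172), within the GH arrays (0.115), with the 3' over 5' covariate (0.0502) and without stem GH 1 and leaf GC 1 (0.0762). The anther and pollen call was kept in 18 of 25 and lost without leaf GC 1 (adjusted p = 0.0622), flower GC 1 (0.0530) or flower GC 2 (0.0632). It was also lost with the filter at the 60th percentile (adjusted p = 0.172), within the GH arrays (0.135), with the 3' over 5' covariate (0.0502) and without stem GH 1 and leaf GC 1 (0.0651).

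Falls in flower covered 16 of 29 nuclear chloroplast genes, with 1 higher, 14 of 33 plastid-encoded photosynthesis genes, 7 of 10 plastid ndh genes and 4 of 19 plastid ribosomal and polymerase genes (adjusted p = 4.4e-07, 4.4e-05, 5.2e-04 and 0.0394). They had adjusted p = 0.111, 0.396, 0.292 and 0.530 with an estimated correlation. Examples were petN of the cytochrome b6f complex (-1.73 ± 0.28), ndhC (-1.04 ± 0.16) and rps19 (-1.16 ± 0.24). The mean log2 3' over 5' ratio was 0.53 to 0.90 on the flower arrays and 0.01 to 0.24 on the stem arrays other than stem GH 1, where it was 2.13. Within the GH arrays petN and rps19 lost their calls (adjusted p = 0.0669 and 0.0719). The ribosomal and polymerase call was kept in 16 of 25 alternatives and lost with quantile normalization and with centring (adjusted p = 0.418 and 0.0557), and without flower GC 2, flower GH 1, stem GC 1 or stem GC 2 (0.131, 0.108, 0.0773 and 0.0831), with these ratios as a covariate (0.0863), with the filter at the 60th percentile (0.101) and within the GH arrays (0.135). The TBL family fell in 5 of 15 cases and rose in 2, with TBL38 at -2.24 ± 0.15 and TBL39 at 1.00 ± 0.16 (adjusted p = 0.0281, and adjusted p = 0.201 with an estimated correlation), and lost the call with the filter at the 60th percentile (0.0704) and within the GH arrays (0.127). Of 7 xyloglucan endotransglucosylases 3 fell, with XTH18 at -4.05 ± 0.48 (adjusted p = 0.0213, and adjusted p = 0.201 with an estimated correlation).

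For flower against stem limma called 6421 probe sets, 4008 higher and 2413 lower in flower, with 2219 and 1231 of these changed at least 2-fold. The median log2 difference of all probe sets was 0.17 as deposited, -0.01 after quantile normalization and 0.02 after centring, where the split was 3171 to 2958 and 3200 to 3056. Within the GC arrays 4257 probe sets differed, and 2976 within the GH arrays.

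The title code GH was compared with GC over the tissues and within each. GAMMA-VPE, a vacuolar processing enzyme, was lower on all 6 GH arrays than on any GC array, with signals of 331 to 549 against 818 to 964. Its log2 fold change was -1.04 ± 0.12 (adjusted p = 0.0309), and it was the only one of 15718 probe sets that limma called, while 1623 had an unadjusted p under 0.05. It kept the call in 9 of 22 alternatives, with an adjusted p of 0.00347 to 0.298, and lost it with centring on the 75th percentile, with eBayes without the trend, with a replicate block and with flower and stem only. With single arrays left out, its call held without leaf GC 1 and without stem GH 1, and each of the other 9 omissions ended it, with an adjusted p of 0.0504 to 0.196. The count was 13 without leaf GC 1, 1 without stem GH 1 and 1, another probe set, without flower GC 1. The 6 light harvesting and photosystem genes lay lower in GH as a list (adjusted p = 0.00334, and adjusted p = 0.319 with an estimated correlation), with none called singly over all probe sets, 1 adjusted over the list alone, and LHCB4.2 at -0.60 ± 0.11.

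In flower, 3 named genes were lower on the GH arrays. AT1G54050, a class III small heat shock protein, had signals of 1854 and 495 on the GC arrays and 46.1 and 33.9 on the GH arrays, a log2 fold change of -4.60 ± 0.55 (adjusted p = 0.0387). AT5G48570, a heat-inducible immunophilin (-3.57 ± 0.37), and Fes1A, a partner of heat shock protein 70 (-2.91 ± 0.33), fell as well (adjusted p = 0.0340 for both). These and 1 unnamed probe set that rose were the 4 calls, against 763 with an unadjusted p under 0.05. With the flower arrays fitted alone limma called 0 (967 with an unadjusted p under 0.05), with eBayes without the trend 1, which was none of these 3 genes, and without flower GC 1 it called 0, with AT1G54050 at -3.65, AT5G48570 at -3.34 and Fes1A at -2.38. The count was also 0 without either leaf GH array, without flower GH 2 and without any single stem array, 7 without flower GH 1 and 10 without flower GC 2, and over 20 alternatives the adjusted p of AT1G54050 ran over 0.0145 to 0.321, of AT5G48570 over 0.0153 to 0.266 and of Fes1A over 0.0145 to 0.275.

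Also in flower, light harvesting and photosystem genes (PSBY, -0.63 ± 0.18), expansin and xyloglucan remodelling genes (EXPA15, -0.68 ± 0.33) and cold and drought genes (COR15B, -0.82 ± 0.28) lay lower as lists (adjusted p = 2.4e-04, 0.0237 and 0.00622), each with adjusted p = 0.327 with an estimated correlation. None of the members passed singly over all probe sets, and adjusted over the list alone 1, 0 and 2 did. The expansin call was lost without flower GC 1 (adjusted p = 0.245) and without flower GH 2 (adjusted p = 0.379), and the cold and drought call without flower GC 2 (adjusted p = 0.0668) and without flower GH 1 (adjusted p = 0.107). The flower GH arrays were also those with the higher mean log2 3' over 5' ratios, 0.90 and 0.80 against 0.53 on both GC arrays, and with these ratios as a covariate the expansin call was lost (adjusted p = 0.0618), as it was with the floor at the dim limit (0.0556). The list's median log2 fold change stayed below 0 in all 20 alternatives, at -1.10 to -0.26, and the cause of the lost calls was not tested. The XTH family, a separate list, lay higher on the GH flower arrays, as given under other observations.

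**Figure D4:**
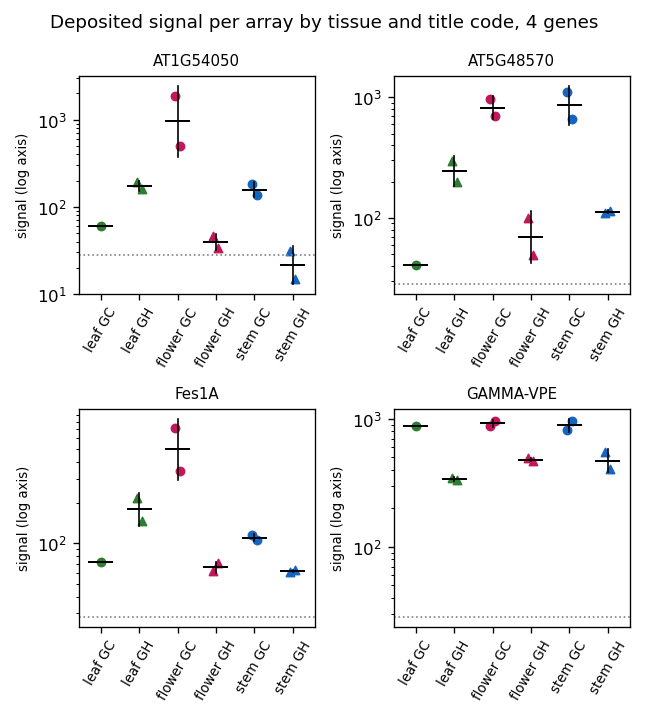
Deposited signals of AT1G54050, AT5G48570, Fes1A and GAMMA-VPE (vertical log axis) are shown per array by tissue and title code (horizontal axis), with the dotted line at the dim limit of 28.1. Horizontal bars are means and vertical bars 1 SD of the log2 signals, with no SD for the single leaf GC array; GAMMA-VPE lies between 331 and 549 on the GH arrays.

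In stem, limma called 13 probe sets, 8 higher and 5 lower on the GH arrays, with 1825 at an unadjusted p under 0.05. ARL, an ARGOS-like regulator of organ growth (1.78 ± 0.23, adjusted p = 0.0307), AT2G27060, a leucine-rich repeat kinase (1.67 ± 0.23, adjusted p = 0.0442), and LCR69, a defensin family gene (1.52 ± 0.18, adjusted p = 0.0242), rose on the log2 scale. AT5G48570 (-2.94 ± 0.37, adjusted p = 0.0295) and GUT2 (-1.45 ± 0.20, adjusted p = 0.0442) fell. The 3 secondary wall genes lay lower as a list, with GUT2 alone called, also adjusted over the list alone (adjusted p = 0.0208, and adjusted p = 0.266 with an estimated correlation). The list's call was lost without stem GC 1 (adjusted p = 0.0756), without stem GC 2 (adjusted p = 0.0507) and without stem GH 2 (adjusted p = 0.176). The balance of directions turned between settings: 7 were higher and 30 lower without stem GH 1, the array with the actin ratio of 19.6, 6 and 24 with the 3' over 5' covariate, 362 and 793 without stem GH 2, 28 and 4 without stem GC 1, and 22 and 4 without stem GC 2. The count was 4 without either leaf GH array and 2 without either flower GC array. It was 0 with stem arrays alone (918 with an unadjusted p under 0.05) and with values floored at the dim limit (1755 with an unadjusted p under 0.05), and the 5 named genes kept their call in 4 to 10 of 20 alternatives. With the 3' over 5' covariate all 5 lost it, LCR69 with the lowest adjusted p (0.0579) and AT2G27060 with the highest (0.120). Their log2 fold changes kept their direction in all 20 alternatives. The ranges were 1.53 to 2.03 for ARL, 1.45 to 1.84 for AT2G27060 and 1.33 to 1.67 for LCR69. They were -3.31 to -2.56 for AT5G48570 and -1.60 to -1.25 for GUT2.

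In leaf, the lone GC array was assumed to vary like the other groups. Limma called 37 probe sets, 25 higher and 12 lower on the GH arrays, with 1519 at an unadjusted p under 0.05. AT4G19430 (2.67 ± 0.38, adjusted p = 0.0300) and AT3G17800 (1.52 ± 0.22, adjusted p = 0.0324) rose, and the lipid transfer family gene AT5G48490 (-3.31 ± 0.42, adjusted p = 0.0261), AT5G02160 (-2.35 ± 0.36, adjusted p = 0.0410) and the universal stress protein AT3G62550 (-1.96 ± 0.29, adjusted p = 0.0379) fell. The count was 3 without leaf GH 2, 13 without leaf GH 1, 24 without either flower GC array, 86 without stem GH 1 and 83 without stem GH 2, and none of the 5 genes kept its call without leaf GH 1 or without leaf GH 2 (adjusted p from 0.0885 to 0.175).

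Lists of plastid genes, chosen after the annotation was read, lay higher on the GH arrays of leaf: photosynthesis genes (psaC, 2.92 ± 0.75), ndh genes, and ribosomal and polymerase genes (adjusted p = 0.00106, 2.4e-04 and 2.4e-04), with adjusted p = 0.732, 0.649 and 0.688 with an estimated correlation. Without leaf GH 2 the adjusted p of the photosynthesis list was 0.449 and that of the ribosomal list 0.0557. The mean log2 signals of the plastid photosynthesis genes were 8.32 on leaf GC 1, 8.65 on leaf GH 1 and 9.56 on leaf GH 2. In the same order the mean log2 3' over 5' ratio was 0.09, -0.03 and -0.24. The 25S ribosomal RNA signal was 8.04, 0.781 and 0.576, and the 5S signal 1.73, 3.33 and 6.47. These ribosomal signals all lay under the dim limit of 28.1 and were not read as a difference between the leaf arrays. Of the genes in these lists ndhH alone passed the test, and the floor at the dim limit ended its call (adjusted p = 0.515), since its signal on the GC array was 1.60. Defensin family genes, among which LCR72 was dim on every leaf array, and ATG8 genes, with ATG8E at -1.47 ± 0.33, lay lower (adjusted p = 7.9e-04 and 0.00528, and adjusted p = 0.319 and 0.688 with an estimated correlation), and the defensin call was lost with the floor (adjusted p = 0.178).

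Whether the GH effect differed between flower and stem was tested directly. Limma called 0 of 15718 probe sets, with 761 at an unadjusted p under 0.05 and a smallest adjusted p of 0.192, and 4 with eBayes without the trend. In simulated data this comparison found 0% of 2-fold and 36% of 4-fold changes. AT5G48570 fell in both tissues, and its difference between them was not called. Without stem GH 2 the count was 210.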

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

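The list of other heat-induced genes was written only after the 3 called genes had been seen. It held 41 genes, of which 14 are on named probe sets and 10 were kept and tested. The tests of flower and of stem against leaf and the tests with floored values were chosen only after the result was seen.

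AT1G54050, AT5G48570 and Fes1A were lower on the GH flower arrays. The median log2 fold change of 10 other heat-induced chaperone genes there was -2.15, or -1.08 with values floored at the dim limit, and 9 lay below 0, with 0 called singly by limma (camera p = 5.4e-11, and p = 0.0105 with an estimated correlation or 0.0538 when floored). A 3' bias of the flower RNA could not be decided, since within flower the ratio moved with the code. The mean log2 ratio was 0.53 on both GC flower arrays, and 0.90 and 0.80 on the GH ones. The slope of the ratio covariate therefore rested mostly on stem GH 1 (2.13) against stem GH 2 (0.24), and a 3' bias stayed open. With the ratio covariate the median of the 3 genes was -3.58. With it AT1G54050 and AT5G48570 kept their calls (adjusted p = 0.0418 for both), while Fes1A went from -2.91 ± 0.33 to -2.91 ± 0.35 (adjusted p = 0.0608) and its call ended: its fold stayed, its unadjusted p went from 6.5e-06 to 2.3e-05 with a larger SE and a degree of freedom spent on the covariate, and their shares in this were not separated. A lower heat response in the GH flower samples is a candidate explanation, and what the codes stood for, and the time of sampling, stayed open and untested.

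The GH effect on these 10 genes was also compared between tissues, against a leaf effect that rests on 1 GC array. Flower minus leaf had a median log2 difference of -3.14 (9 of 10 below 0, camera p = 8.5e-10, p = 0.0137 with an estimated correlation), or -1.71 floored (camera p = 5.5e-09, p = 0.0442 with an estimated correlation). Stem minus leaf had -2.44 (9 of 10 below 0, camera p = 7.6e-06, p = 0.0420 with an estimated correlation), or -0.82 floored (camera p = 7.6e-05, p = 0.1295 with an estimated correlation). In leaf the median was 1.29 (p = 0.0867 with an estimated correlation), or 0.63 floored (p = 0.164), and in stem it was -1.46 (p = 0.128), or -0.26 floored (p = 0.393).

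A single array lay far from the other 3 of its tissue in 15 of 196 tests of named genes and 4 of 16 tests of quality measures, where chance gives about 1 in 20 groups. The gap to the nearest array as a share of the range is given for each. For genes the share was taken on log2 signals, though signals are printed on the linear scale. For quality measures it was taken on the linear values. On stem GH 1 the share was 0.991 for the actin ratio (19.6 against 1.22 to 1.37), 0.891 for the GAPDH ratio (1.77 against 0.787 to 0.894) and 0.898 for the bioB spike (237 against 159 to 167). The genes apart on stem GH 1 were AT4G21650 (0.913, signal 834 against 1073 to 1099), AT5G50030 (0.912, 43.2 against 26.0 to 27.2), RCA (0.910, 6228 against 4367 to 4509), HPR (0.930, 2548 against 1458 to 1516), GH9B5 (0.862, 654 against 436 to 461) and TUB9 (0.967, 1238 against 1025 to 1032). On stem GH 2 the share was 0.891 for 25S ribosomal RNA (6.39 against 11.5 to 12.1). AT4G19430 stood apart on stem GC 2 (0.895, 15.6 against 29.3 to 31.6) and SWEET9 on stem GC 1 (0.947, 37.7 against 23.4 to 23.995), and signals under the dim limit of 28.1 among these and in AT5G50030 were not read as expression.

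Among flower arrays, flower GC 2 stood apart for LCR69 (0.835, 2709 against 2092 to 2183) and AT5G48490 (0.869, 252 against 127 to 139), and flower GC 1 for AT3G22240 (0.850, 457 against 356 to 369.5). Flower GH 2 stood apart for GILT (0.933, 574 against 1220.1 to 1288), and flower GH 1 for GUT2 (0.904, 53.1 against 60.5 to 61.3) and AT3G62550 (0.886, 397 against 497 to 512). The share for AT5G59540 on flower GC 2 was 0.947, with all 4 signals (3.68 against 9.81 to 10.4) under the dim limit of 28.1, so the gap says nothing of expression there.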

How the results depend on the processing

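The covariate for the 3' over 5' ratios and leaving out stem GH 1 and leaf GC 1 together were tests chosen only after the result was seen. In the tissue comparisons counts stayed within 1.5 times under every alternative except within one code: within the GC arrays they were 2612 (flower against leaf), 3027 (stem against leaf) and 4257 (flower against stem), and within the GH arrays 2976 (flower against stem), with fewer arrays in each. With a replicate block they were 5207, 5811 and 6186, though the numbers did not pair the samples. Leaving out each array gave 4407 to 6288, 4923 to 6247 and 5368 to 6579. List calls numbered 11, 14 and 16 in the tissue comparisons, 2, 0 and 0 with an estimated correlation and 30, 32 and 31 with fry. For GH over the tissues, in flower, in stem and in leaf they numbered 1, 5, 2 and 5, 0 in each with an estimated correlation, and 0, 0, 3 and 0 with fry.

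The cause of the following changes in the GH against GC counts was not tested. Over the tissues limma called 0 with centring, 0 with eBayes without the trend and 0 with a replicate block (1607, 1505 and 1695 at an unadjusted p under 0.05), 9 with flower and stem only, 16 without stem GH 1 and leaf GC 1, and 0 to 13 with each array left out. In flower it called 9 with a pseudocount, 1 with eBayes without the trend, 0 with flower arrays alone and 0 to 10 with each array left out. In stem it called 8 with quantile normalization, 6 with a pseudocount, 0 with the floor, 0 with stem arrays alone, 30 with the ratio covariate and 2 to 1155 with each array left out. In leaf it called 81 with the ratio covariate and 3 to 86 with each array left out, and leaving out leaf GC 1 was not run because no GC array would remain. The GH effect in flower against stem had 4 calls with eBayes without the trend and 0 to 210 with each array left out. The plastid-encoded photosynthesis list over the tissues, not called as deposited, reversed to a median log2 fold change of 0.20 with the ratio covariate (adjusted p = 0.0133). Signals under the dim limit of 28.1 limited folds to lower bounds.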

Other observations

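Among these observations, the test of nuclear chloroplast genes and the counts without stem GH 1 and leaf GC 1 were tests chosen only after the result was seen. A widened list of 9 measured xylan and secondary wall genes, drawn up after the annotation was read, had 6 genes higher and 0 lower in stem than leaf (adjusted p = 0.00674, and adjusted p = 0.133 with an estimated correlation). Between flower and stem 1 of these genes was higher and 6 were lower in flower (adjusted p = 0.00295, and adjusted p = 0.111 with an estimated correlation). On the GH flower arrays the XTH family lay higher (adjusted p = 0.0213, and adjusted p = 0.699 with an estimated correlation), and without flower GC 1, without flower GH 2 or with flower arrays alone its adjusted p was 0.146, 0.478 or 0.0847. Nuclear chloroplast genes lay lower there (adjusted p = 7.7e-04, and adjusted p = 0.699 with an estimated correlation), and without flower GH 2 the adjusted p was 0.105. On the GH stem arrays plastid-encoded photosynthesis genes lay lower (adjusted p = 0.0454, and adjusted p = 0.977 with an estimated correlation), and the call was kept in 13 of 20 alternatives. Its adjusted p was 0.513 without stem GH 1, the array with the actin ratio of 19.6, 0.172 without stem GC 1, 0.178 without stem GC 2, 0.0515 without flower GC 1, 0.0513 without flower GC 2, 0.0807 with eBayes without the trend and 0.962 with the 3' over 5' covariate.

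With flower and stem only, 9 probe sets were lower in GH. The 4 that name 1 gene were AT5G48570 (-3.25 ± 0.26), AT1G30070 (-2.16 ± 0.25), AT1G54050 (-3.73 ± 0.47) and AT4G30490 (-1.08 ± 0.15). Without stem GH 1 and leaf GC 1, 16 were lower, of which 7 name 1 gene, including GAMMA-VPE (-1.02 ± 0.11), the lipocalin TIL (-1.27 ± 0.15) and AT5G12110 (-1.48 ± 0.21). AT1G30070, AT4G30490, TIL and AT5G12110 were singled out after their values were seen.

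Of 33 plastid-encoded photosynthesis genes 16 were called higher in stem than leaf and 28 had a log2 fold change above 0, with a median of 1.13 (adjusted p = 1.1e-04, and adjusted p = 0.434 with an estimated correlation). Under a 3' bias of the stem RNA the difference would be lost with correction, and with the ratio covariate the median was 1.76. The slope of that covariate rested mostly on stem GH 1, at 2.13 against 0.01 to 0.24 on the other stem arrays. Stem GH 1 also had the lowest plastid mean in stem, 9.50 against 10.19 to 10.31. The covariate therefore cannot decide on a 3' bias. Without stem GH 1 the median was 1.43, so the difference did not rest on that array. Nuclear chloroplast genes did not rise with the plastid-encoded ones, at a median of -0.77. Nuclear transcripts were not shown here to follow the number of chloroplasts, so this does not decide on more chloroplasts in the stem sample. Whether a low leaf GC array accounts for part of the difference stayed open. Within the GH arrays the median was 0.53, between the bounds set for that test. That fit also left out both GC stem arrays and kept stem GH 1, so the lower median cannot be assigned to leaf GC 1. Without leaf GC 1 alone the median was 0.71, with 13 genes called higher, and within the GC arrays it was 2.02. The mean log2 signal of these genes was 8.32 on leaf GC 1, 8.65 on leaf GH 1 and 9.56 on leaf GH 2. The number of arrays did not allow a decision. The differences between leaf and stem in age and in 5S ribosomal RNA signal (1.73 to 6.47 against 49.4 to 196) were not tested as causes. Whether the plastid signals follow the amount of plastid transcript was not tested either.

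Calls were counted in other splits of the same arrays. In the tissue comparisons only the real split of 35 had as many calls, a share of 2.86%, the smallest that 35 splits allow. The counts were 5617 against at most 54 in flower and leaf, 6222 against at most 1222 in stem and leaf, and 6421 against at most 6 in flower and stem. Every other split mixed the tissues within groups, and replicates may be technical, so these counts do not exclude chance between plants. For GH over the tissues 4 of the 100 splits run, of 108 possible, had at least the 1 call of the real one, a share under 0.05 that rests on a single call. The highest other split had 14. Whether a structure of the samples lies behind this was not tested, and chance is not taken as excluded for the call.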
